A study of Mus musculus with 10 samples.

How the data were processed

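Gene expression was measured by RNA sequencing in 10 libraries of mouse trigeminal ganglion in 2 experiments. In the first, 3 sham and 3 pIONT libraries came from ganglia taken on day 10 after surgery. In the second, 2 PBS and 2 UCN1 libraries came from ganglia taken 6 hours after an injection into the ganglion. The table columns of the injection experiment are numbered 1 and 3 in each group, while the titles number the same libraries 1 and 2. Whether further libraries were made and left out is not given in the sources used here, and p-values take the 2 per group as they are. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra II RNA kit. Whether the kit or the counting kept the strand is not given in the sources used here.

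The authors deposited 1 table per experiment, in FPKM (reads scaled by gene length and library depth). The submitters' processing notes name STAR, HTSeq, DESeq2 and the build GRCm39, with no version, role or parameter. The table of the surgery experiment held 26411 genes, and none of them was at 0 in every library. Of its 25174 gene identifiers found in GENCODE vM21 (build GRCm38), 502 (1.99%) had the same start and end there. The table of the injection experiment held 55886 genes, of which 27742 were at 0 in every library. Of its 55141 identifiers found in the same annotation, 99.42% had the same start and end, so its coordinates are those of GRCm38 and not of the build in the notes. Gene symbols were taken from the GENCODE vM21 name table by identifier, for 25166 and 55141 identifiers. Features without a symbol there were tested but are not named.

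The low FPKM values were whole multiples of a step in each library once multiplied by a gene length, within a tolerance of 0.1 reads and up to 20 reads. With the union of exons as length, 92.4% to 92.9% of low values were whole in the surgery experiment. With the mean length of the transcripts, 98.8% to 99.0% were whole in the injection experiment. The authors' tables therefore differ in their definition of length as well as in annotation, and FPKM levels were not compared across them. All tests were made within a table. The steps gave a depth of 24.1 to 29.6 M reads in genes per library in the surgery experiment and 15.7 to 17.1 M (M for 1e6 reads) in the injection experiment.

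Genes with a mean FPKM of at least 0.5 over the libraries of an experiment were tested with limma 3.58.1 in R 4.3.3, on log2(FPKM + 0.5), with a mean-variance trend and no covariate. The threshold was a Benjamini-Hochberg adjusted p of 0.05, and such genes are said to be called. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes. The labels do not say whether libraries came from separate animals or pools, so p-values measure only the spread between these samples, which may be technical. Libraries of a group differed by far more than sampling noise, with a chi-square per degree of freedom of 6.21 to 16.1, and none was treated as a duplicate.

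Before the data were examined, 28 gene lists of 411 genes were written from general knowledge of the ganglion, of nerve injury and of tissue that dissection can carry over. Lists with at least 3 tested members were tested with camera in limma, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation was run beside it. That version also judges its statistic on the residual degrees of freedom, 4 in the surgery and 2 in the injection experiment. It therefore has little power here, and a lost call does not show that a list did not move. Fry in limma, which tests the genes of a list without setting them against other genes, was run as well. Calls within a list were also counted with p-values adjusted over the list alone. Genes called in the surgery experiment were tested as sets in the injection experiment, and the overlap of calls was tested with Fisher's exact test, two-sided, with 95% confidence intervals. Intervals from reads cover counting error only.

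The rule for the genes named was also fixed before the data were examined. It took the peptides and receptors of the corticotropin-releasing factor (CRF) family and Hspb1. It took the 10 genes with the largest increase and the 10 with the largest decrease among called genes with no overlap between the groups' libraries and a mean of at least 1 FPKM in a group. Predicted genes, Rik clones and pseudogenes were passed over. From each list it took up to 4 called members by smallest p, or else up to 2 members with the highest level, and it took up to 10 genes called in both experiments. Single values of some genes that the rule took are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

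The limma test was tested on simulated data made from the recovered reads, with a dispersion of 0.02 and 200 changed genes. Over 14452 genes for the surgery experiment it called 93.8% of 2-fold and 100% of 4-fold changes, and 11.2% of its calls were false. Over 15791 genes for the injection experiment it called 37.4% of 2-fold and 91.5% of 4-fold changes, and 12.8% of its calls were false. Limma-voom on the same simulated reads had fewer false calls, 3.6% and 4.9%, and called 93.9% and 66.7% of 2-fold changes. The simulation gave every gene the same dispersion, had no library that stood apart and changed 200 genes, against 3344 called after surgery. These rates may therefore not hold for the real libraries. The test on log2 FPKM was kept as the one fixed before the data were examined. The alternatives were pseudocounts of 0.1 and 1, no filter and a filter at 2 FPKM, rescaling by median of ratios, to TPM and by quantiles, no variance trend, array weights, a replicate block, a fold threshold and leaving out each library. Limma-voom on recovered reads and a filter of at least 10 recovered reads were added after seeing the data. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.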

Results

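RNA of the mouse trigeminal ganglion, which holds the sensory neurons of the face with their glia, was sequenced in 10 libraries. The surgery experiment had 3 libraries of sham-operated mice and 3 of mice with the surgery that the labels call pIONT, taken on day 10. The injection experiment had 2 libraries after phosphate-buffered saline (PBS) and 2 after urocortin 1 (UCN1), a peptide of the CRF family, each injected into the ganglion 6 hours earlier. Depth in genes was 27.4, 28.7 and 24.1 M reads (M for 1e6) for sham 1 to 3 and 25.6, 29.2 and 29.6 M for pIONT 1 to 3. It was 15.7 and 17.0 M for the PBS libraries and 17.1 and 16.5 M for the UCN1 libraries. The series title names urocortin 1, the small heat shock protein HSPB1 and neuropathic pain, so the values of Ucn, which encodes urocortin 1, and Hspb1 are given for both experiments.

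The first comparison asked which transcripts differed in the ganglion 10 days after pIONT. Ucn rose from 0.0274 ± 0.0475 FPKM in sham to 3.47 ± 0.591 in pIONT (SD, n = 3), with a log2 fold change of 2.91 (SE 0.13, limma adjusted p = 4.45e-05). Hspb1 rose from 195 ± 1.45 to 335 ± 32.5 FPKM (SD, n = 3), a log2 fold change of 0.77 (SE 0.07, limma adjusted p = 0.00086). All 26 tested genes of the list of the nerve injury response of sensory neurons rose, and 10 of 19 macrophage genes rose, with Ctss at 128 FPKM in pIONT 2 against 53.1 and 48.7 in the other pIONT libraries. Of potassium channel genes 16 of 23 fell and of myelinating Schwann cell genes 7 of 13. The set calls of all 4 lists were lost with an estimated correlation (limma camera adjusted p = 0.474, 0.737, 0.737 and 0.474 in this order).

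Ucn lies on chromosome 5 at 31295407 to 31296173 and Hspb1 on chromosome 5 at 135916773 to 135918417, as the table of the surgery experiment gives them. The Ucn value rests on few reads, 1 in the 3 sham libraries together and 40 to 61 in each pIONT library. The ratio of read rates was 141, with a 95% exact interval of 24.9 to 5600 for counting error. Among the other CRF peptides and receptors, Crhr1, a receptor of CRF and urocortin 1, fell by 0.54 on the log2 scale (limma adjusted p = 0.0287), a call kept in 13 of 18 alternatives. Crhr2, which binds the urocortins, fell by 0.47 (limma adjusted p = 0.048), a call kept in 6 of 17 alternatives. Crh and Ucn2 had log2 fold changes of 1.22 and 0.86 and did not pass (limma adjusted p = 0.0707 and 0.0942), although Crh was called without pIONT 3, at 1.72 (limma adjusted p = 0.0038). Crhbp was below the filter, at means of 0.183 and 0.264 FPKM. Of the 5 tested members 1 rose and 2 fell, or 3 and 2 adjusted over the list alone, and the list as a whole was not called (limma camera adjusted p = 0.419).

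**Figure D1:**
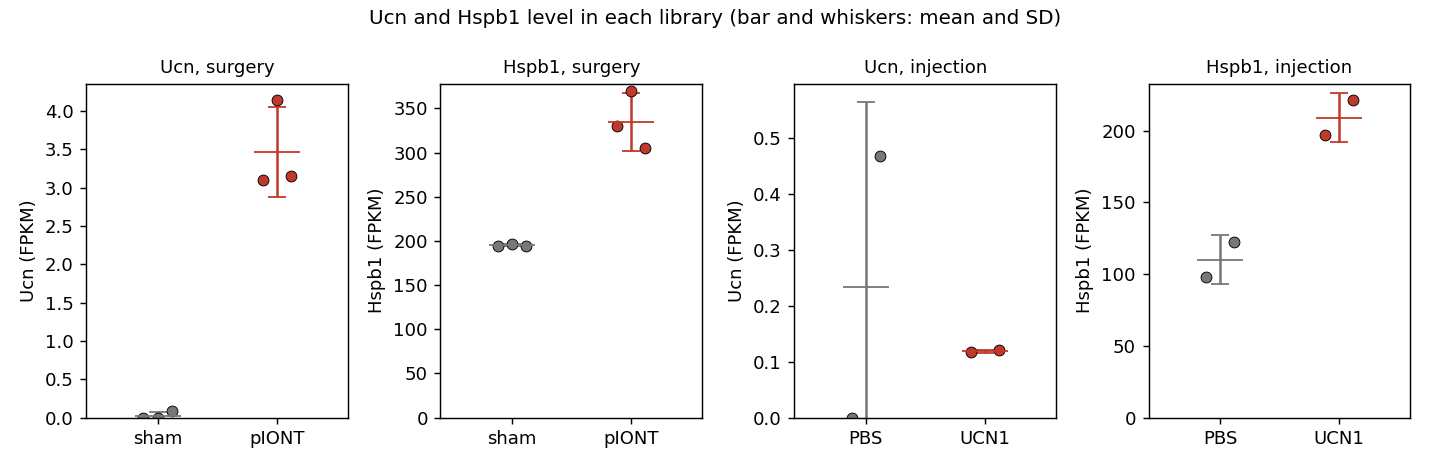
Level of Ucn and Hspb1 in FPKM (vertical axes) in each library of both experiments, as points by group, with the group mean as a bar and the SD as whiskers. The 3 pIONT libraries lie above the 3 sham libraries for both genes, and Hspb1 averaged 110 FPKM in PBS and 209 FPKM in UCN1 libraries, while levels are not comparable across the experiments.

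Of 14672 genes tested, 1537 were higher and 1807 lower in pIONT, and of these 220 and 17 changed at least 2-fold. At an unadjusted p of 0.05, 5434 genes passed, against 734 by chance. In 3342 of the 3344 called genes the libraries of the groups did not overlap, a pattern held by 43.4% of all tested genes and by 10% by chance. The largest increases were Sprr1a, a cornified envelope protein made by injured sensory neurons, at 9.62, and the neuropeptides Npy at 8.04, Gal (galanin) at 6.56 and Nts (neurotensin) at 5.50 on the log2 scale. Next came the orphan receptor Gpr151 at 5.43, the stress transcription factor Atf3 at 5.03, the serotonin transporter Slc6a4 at 4.99, the endopeptidase Ecel1 at 4.65, the lipase Lipn at 4.19 and Fst (follistatin) at 3.89. This order holds on the log2(FPKM + 0.5) scale only, and across the alternatives Lipn reached 8.39 and Slc6a4 7.35 while Gal reached at most 6.76 and Nts 5.75. Sprr1a went from 0.134 ± 0.0822 to 499 ± 81.4 FPKM and Gal from 10.6 ± 2.21 to 1082 ± 389 FPKM (SD, n = 3). The largest decreases were the calcium-binding proteins Calb2 and Pvalb at -2.02 and -1.41, with Retnla, a macrophage-derived secreted protein, at -1.57. Rem2, Tceal6, Fbxo40, Glb1l2, Cdkl4, Tmem196 and the transcription factor Mafa had values of -1.34 to -1.11. Calb2 fell from 59.2 ± 4.92 to 15.2 ± 6.39 FPKM (SD, n = 3, limma adjusted p = 0.00604).

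In the nerve injury list the median log2 fold change was 2.51 (limma camera adjusted p = 2.35e-34, and adjusted p = 0.474 with an estimated correlation). Sprr1a, Nts, Gpr151 and Ecel1 had the smallest p of its members, and all 26 also passed adjusted over the list alone. In the list of voltage-gated and background potassium channels 16 of 23 genes fell, 17 adjusted over the list alone with 2 higher (median -0.32, limma camera adjusted p = 7.69e-05, and adjusted p = 0.737 with an estimated correlation). Kcnk1, a background channel, fell by 0.83, Kcns3 by 0.75, Kcna2 by 0.58 and the sodium-activated channel Kcnt1 by 0.49. In the nociceptor list 8 of 22 genes fell and 1 rose, as many adjusted over the list alone (median -0.16, limma camera adjusted p = 0.0134, and adjusted p = 0.816 with an estimated correlation). The cold receptor Trpm8 fell by 1.10 and the peptide gene Calcb by 0.29, while the artemin co-receptor Gfra3 rose by 0.44. That list was not called without sham 2 or without pIONT 2. Of 15 pan-neuronal genes 5 rose and 7 fell, 9 adjusted over the list alone, and the list was not called (limma camera adjusted p = 0.488). The cytoskeletal genes Stmn2 and Tubb3 rose by 1.28 and 0.89 and Thy1 by 0.33, and Vsnl1, a neuronal calcium sensor, fell by 0.82.

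In the myelinating Schwann cell list 7 of 13 genes fell and 0 rose, 10 lower adjusted over the list alone (median -0.27, limma camera adjusted p = 0.00124, and adjusted p = 0.474 with an estimated correlation). The myelin genes Mbp, Pmp22 and Ncmap fell by 0.43, 0.34 and 0.36 on the log2 scale and Fa2h, which makes myelin lipids, by 0.45. Among 8 genes of non-myelinating and repair Schwann cells only the adhesion molecule Ncam1 was called, at 0.32, also adjusted over the list alone (limma camera adjusted p = 0.403). Of 12 satellite glia genes 2 rose and 2 fell, 3 and 2 adjusted over the list alone (limma camera adjusted p = 0.745). Glul (glutamine synthetase) and Cdh19 rose by 0.31 and 0.16, and Bcan and Sparcl1 fell by 0.40 and 0.27.

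The macrophage list had 10 of 19 genes higher, 14 adjusted over the list alone (median 0.98, limma camera adjusted p = 3.25e-05, and adjusted p = 0.737 with an estimated correlation). The protease Ctss rose by 1.97, the lipid receptor Trem2 by 1.67, the fractalkine receptor Cx3cr1 by 1.24 and the growth factor receptor Csf1r by 1.08. pIONT 2 stood apart, with Lyz2 at 449 FPKM against 164 and 142 in the other pIONT libraries and Col1a1 at 73.9 FPKM against 34.7 and 35.9, genes chosen after their values were seen. In the list of fibroblasts and extracellular matrix only Timp1 of 15 genes rose, at 1.64, a call kept in 9 of 18 alternatives, and 0 adjusted over the list alone (median 0.41, limma camera adjusted p = 0.00839, and adjusted p = 0.816 with an estimated correlation). Of 12 damage signal receptors 5 rose, and 5 with 1 lower adjusted over the list alone (median 0.19, limma camera adjusted p = 0.00909, and adjusted p = 0.737 with an estimated correlation). They included the interleukin-1 receptor Il1r1 at 0.83, the purine receptor P2ry12 and the lipopolysaccharide co-receptor Cd14 at 0.69 each, and the tumour necrosis factor receptor Tnfrsf1a at 0.39. Of 16 interferon-stimulated genes Mx1 rose by 1.18 and Ifit2 by 0.62, with overlapping libraries for Ifit2, and 1 adjusted over the list alone (median 0.43, limma camera adjusted p = 0.0277, and adjusted p = 0.859 with an estimated correlation). The interferon list was not called in 6 of 18 alternatives, those at 2 FPKM, with array weights, and without sham 2, sham 3, pIONT 2 or pIONT 3.

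Of 11 tested genes of cytokines and acute inflammation Socs3 rose by 0.90 and Cxcl10 by 1.38 on the log2 scale and Nfkbia fell by 0.29, with as many adjusted over the list alone (limma camera adjusted p = 0.0705). Neutrophil, lymphocyte and red blood cell genes had 0 calls, also adjusted over the list alone (limma camera adjusted p = 0.488, 0.99 and 0.403 for 10, 5 and 5 tested genes). Their levels varied within groups, with the neutrophil gene S100a9 at 13.4 to 126 FPKM and the haemoglobin gene Hba-a1 at 49.6 to 202 FPKM in sham libraries.

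Of 14 immediate early and cAMP-responsive genes 4 rose, also adjusted over the list alone (median 0.19, limma camera adjusted p = 0.00909, and adjusted p = 0.737 with an estimated correlation). These were Crem at 0.82, Arc at 0.66, Btg2 at 0.65 and the phosphatase Dusp1 at 0.42, and with voom the list was not called. Of 13 genes of the unfolded protein response 4 rose, also adjusted over the list alone (median 0.13, limma camera adjusted p = 0.0098, and adjusted p = 0.737 with an estimated correlation). They were Trib3 at 0.52, Sdf2l1 at 0.36, the transcription factors Xbp1 at 0.26 and Atf4 at 0.18. Of 22 heat shock proteins and chaperones 2 rose and 3 fell, 3 and 3 adjusted over the list alone (limma camera adjusted p = 0.745). Besides Hspb1, Hspa2 rose by 0.39, and Hsph1 and Dnajb4 fell by 0.25 and 0.21. The calls of Hspa2, Hsph1 and Dnajb4 were kept in 9, 16 and 8 of 18 alternatives.

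In the oxidative stress list the sulfiredoxin Srxn1 rose by 1.36 and Txnrd1 by 0.26, while Nqo1 and Gclc fell by 0.39 and 0.38. There 2 of 9 genes rose and 3 fell, as many adjusted over the list alone (limma camera adjusted p = 0.663). Of 12 glucocorticoid-responsive genes the cell cycle inhibitor Cdkn1a rose by 0.70 and Sgk1 and Tsc22d3 fell by 0.45 and 0.28, with 1 higher and 3 lower adjusted over the list alone (limma camera adjusted p = 0.488). Of 15 genes of cholesterol synthesis 1 rose and 4 fell, 2 and 5 adjusted over the list alone (limma camera adjusted p = 0.403), with Lss, Cyp51 and Dhcr7 at -0.32, -0.27 and -0.21. Of 11 endothelial genes Ly6c1 and Pecam1 fell by 0.20 and 0.24, also adjusted over the list alone (median -0.20, limma camera adjusted p = 0.0237, and adjusted p = 0.474 with an estimated correlation). The endothelial list was not called at a filter of 2 FPKM or without pIONT 1. The lists of the cell cycle, mural cells and skeletal muscle had 0 calls, also adjusted over the list alone (limma camera adjusted p = 0.388, 0.419 and 0.956).

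Genes of the pituitary and of oligodendrocytes and astrocytes of the brainstem root also had 0 calls, also adjusted over the list alone (limma camera adjusted p = 0.488 and 0.695). Sham 1 stood apart in both, with Pomc at 158 FPKM against 1.08 and 2.49 in sham 2 and 3. Mog, a myelin gene of oligodendrocytes chosen after its values were seen, was at 2.68 FPKM in sham 1 against 0.0817 and 0.195. Gh (growth hormone) spread over all 3 libraries, at 546, 74.0 and 243 FPKM in sham 1 to 3. Without sham 1, 2245 genes were called, 1203 higher and 1042 lower.

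All 11 list calls of this comparison were lost with an estimated correlation, a setting with little power here. Fry passed nerve injury, myelinating Schwann cells, endothelium, potassium channels and damage signal receptors (fry adjusted p = 0.000239, 0.00477, 0.00676, 0.0256 and 0.0290). The other called lists did not pass in fry (fry adjusted p = 0.0839 to 0.460). The CRF and oxidative stress lists, not called in camera, passed in fry (fry adjusted p = 0.00477 and 0.0256). Of the other genes named, Atf4, Cdh19, Dhcr7, Sdf2l1 and Nfkbia kept their calls in 8 or 9 of 18 alternatives. The number of genes called fell to 2076 without sham 2 and to 1689 without sham 3. The balance of directions depended on the processing, with 46.0% of calls higher, 36.7% under TPM, 52.1% with no filter, 54.5% after median-of-ratios scaling and 55.1% with voom. Exons of Csf1r, Cdkn1a, Cxcl10, Crem, Kcnk1 and Trpm8 overlap genes on the opposite strand by 5.9% to 15.1% of their bases, so these values may include reads of the other gene.

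The second comparison asked what UCN1 in the ganglion changed within 6 hours. Of heat shock protein and chaperone genes 4 of 22 rose, led by Hspa1b, an inducible HSP70 gene, with a log2 fold change of 1.96 and its co-chaperone Dnajb1 at 1.19. Of genes of the unfolded protein response 2 of 13 rose, and both set calls were lost with an estimated correlation (limma camera adjusted p = 0.234 for each). The estimated correlations of these lists were 0.0056 and -0.044, below the preset 0.01, so a higher correlation is not what lost the calls. Hspb1 rose from 110 ± 17.1 to 209 ± 17.1 FPKM (SD, n = 2), a log2 fold change of 0.93 (SE 0.12, limma adjusted p = 0.0222). The immediate early gene Fos rose by 1.10 and Atf3 by 1.18. The pituitary hormone gene Gh was lower in the UCN1 libraries, at -4.03 on the log2 scale, as was Mfap4, a matrix protein gene, at -4.73.

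Hspb1 lies on chromosome 5 at 135887919 to 135889563 in this table (GRCm38). Its call was kept in 10 of 16 alternatives, with an adjusted p of up to 0.402 in limma. Endogenous Ucn was below the filter, at 0.467 FPKM or less in each library. Crhr1 and Crhr2 had log2 fold changes of -0.16 and -0.19 and did not pass (limma adjusted p = 0.793 and 0.805). These were the only 2 tested members of the CRF list, which was too short for a test.

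Of 16139 genes tested, 49 were higher and 48 lower, and of these 24 and 35 changed at least 2-fold. At an unadjusted p of 0.05, 2113 genes passed, against 807 by chance. The libraries of the groups did not overlap in any of the 97 called genes, a pattern held by 45.5% of all tested genes and by 33.3% by chance. The 10 largest increases included 3 features without a symbol, of which 1 was listed at 0 in both PBS libraries. After Hspa1b they held the microRNA gene Mir8099-2 at 1.69, Gfap, an intermediate filament of activated glia, at 1.66 and Alkal2, a ligand of the receptor ALK, at 1.45. The chemokine receptor Cxcr4 was at 1.28 and the inositol transporter Slc5a3 at 1.20. Mir8099-2 rested on 5 and 3 reads in PBS and 18 and 13 in UCN1 libraries. Exons of Alkal2 overlap a gene on the opposite strand by 35.1% of their bases, and Hspa1b has a near-identical neighbouring copy, so reads may be shared. The same holds for Hmgcs1 and Junb, named below, with overlaps of 12.1% and 7.5%.

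The largest decreases after Mfap4 and Gh were the matrix proteoglycan Fmod at -3.98, the transporter Slc47a1 at -3.24, Prl (prolactin) at -3.15, the carboxypeptidase Cpz at -2.79 and the imprinted RNA H19 at -2.55. This order too holds on the log2(FPKM + 0.5) scale only, and across the alternatives Slc47a1 reached -6.47 while Mfap4 reached at most -5.20. The list also held 1 feature without a symbol and the microRNA genes Mir7211 and Mir5119, which were listed at 0 in both UCN1 libraries and rested on 3 to 6 reads in each PBS library. Mfap4 fell from 42.9 ± 2.80 to 1.15 ± 0.186 FPKM and Gh from 103 ± 1.12 to 5.89 ± 1.01 FPKM (SD, n = 2, limma adjusted p = 8.41e-06 for both).

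Of 22 heat shock proteins and chaperones 4 rose, 13 adjusted over the list alone (median 0.40, limma camera adjusted p = 8.03e-15, and adjusted p = 0.234 with an estimated correlation). Besides Hspa1b, Dnajb1 and Hspb1 this was Serpinh1, a collagen chaperone, at 0.92. Of 13 genes of the unfolded protein response 2 rose, 9 adjusted over the list alone (median 0.44, limma camera adjusted p = 4.81e-11, and adjusted p = 0.234 with an estimated correlation). The chaperone Hspa5 rose from 123 ± 7.05 to 197 ± 12.9 FPKM (SD, n = 2) and Xbp1 by 0.67 on the log2 scale. Of 15 genes of cholesterol synthesis 0 were called, 6 were lower adjusted over the list alone and the log2 fold change of every one was negative (median -0.22, limma camera adjusted p = 1.14e-06, and adjusted p = 0.472 with an estimated correlation). Hmgcs1 and Srebf2, the members with the highest level, were at -0.42 and -0.09.

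In the nerve injury list 1 of 23 genes rose, Atf3, and 6 adjusted over the list alone (median 0.13, limma camera adjusted p = 0.000249, and adjusted p = 0.751 with an estimated correlation). The nociceptor list had 0 of 22 genes called, also adjusted over the list alone, and was called as a set (median 0.11, limma camera adjusted p = 0.00672, and adjusted p = 0.472 with an estimated correlation), with Calca at 0.28 and Ret at 0.07. Of 15 immediate early and cAMP-responsive genes 2 rose, Fos and Junb, the latter by 0.80, and 3 rose and 1 fell adjusted over the list alone (median 0.09, limma camera adjusted p = 0.0225, and adjusted p = 0.801 with an estimated correlation). Of 10 genes of cytokines and acute inflammation Socs3, an inhibitor of cytokine signalling, rose by 0.99, also adjusted over the list alone (median 0.51, limma camera adjusted p = 0.0196, and adjusted p = 0.801 with an estimated correlation). The immediate early list was not called without PBS 2 or UCN1 1, and the cytokine list not without a filter, without PBS 2 or without UCN1 2.

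The pituitary list had 3 of 5 genes lower, Gh, Prl and Pomc, and 4 adjusted over the list alone (median -1.84, limma camera adjusted p = 5.67e-08, and adjusted p = 0.237 with an estimated correlation). In the list of fibroblasts and extracellular matrix Col6a1 fell by 0.83, the only one of 15 genes called, and 2 fell adjusted over the list alone (median -0.17, limma camera adjusted p = 0.0188, and adjusted p = 0.801 with an estimated correlation). The fibroblast list was not called without the variance trend, without PBS 1 or without UCN1 2. Gfap was the 1 called gene of 12 in the satellite glia list, with 2 higher and 1 lower adjusted over the list alone (limma camera adjusted p = 0.193).

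The other lists with at least 3 tested members had 0 called genes and were not called as sets. The limma camera adjusted p was 0.137 for potassium channels, 0.732 for pan-neuronal genes, 0.477 for myelinating Schwann cells, 0.62 for non-myelinating and repair Schwann cells and 0.667 for macrophages. It was 0.477 for neutrophils, 0.575 for damage signal receptors, 0.0905 for interferon-stimulated genes, 0.7 for glucocorticoid-responsive genes and 0.707 for oxidative stress. It was 0.793 for the cell cycle, 0.494 for endothelium, 0.575 for mural cells, 0.26 for red blood cells, 0.7 for skeletal muscle and 0.494 for oligodendrocytes and astrocytes of the brainstem root. Adjusted over the list alone, 1 gene was higher in the lists of non-myelinating Schwann cells, endothelium and red blood cells, 1 higher and 1 lower in skeletal muscle, 1 lower in macrophages and oxidative stress, 2 lower in the glucocorticoid list and 0 in the others. Of lymphocyte genes only 2 were tested, which was too few for a set test. Fry passed heat shock, pituitary, the unfolded protein response and nociceptors (fry adjusted p = 0.0127, 0.0127, 0.0130 and 0.0130). The other lists called in camera did not pass in fry (fry adjusted p = 0.163 to 0.623).

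With 2 libraries per group the number of called genes moved with the settings, from 2 with no filter to 375 with voom on recovered reads. Of the genes named, only Gh and Mfap4 were called in all 16 alternatives. Without PBS 1, PBS 2, UCN1 1 and UCN1 2 it was 38, 20, 7 and 5.

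**Figure D2:**
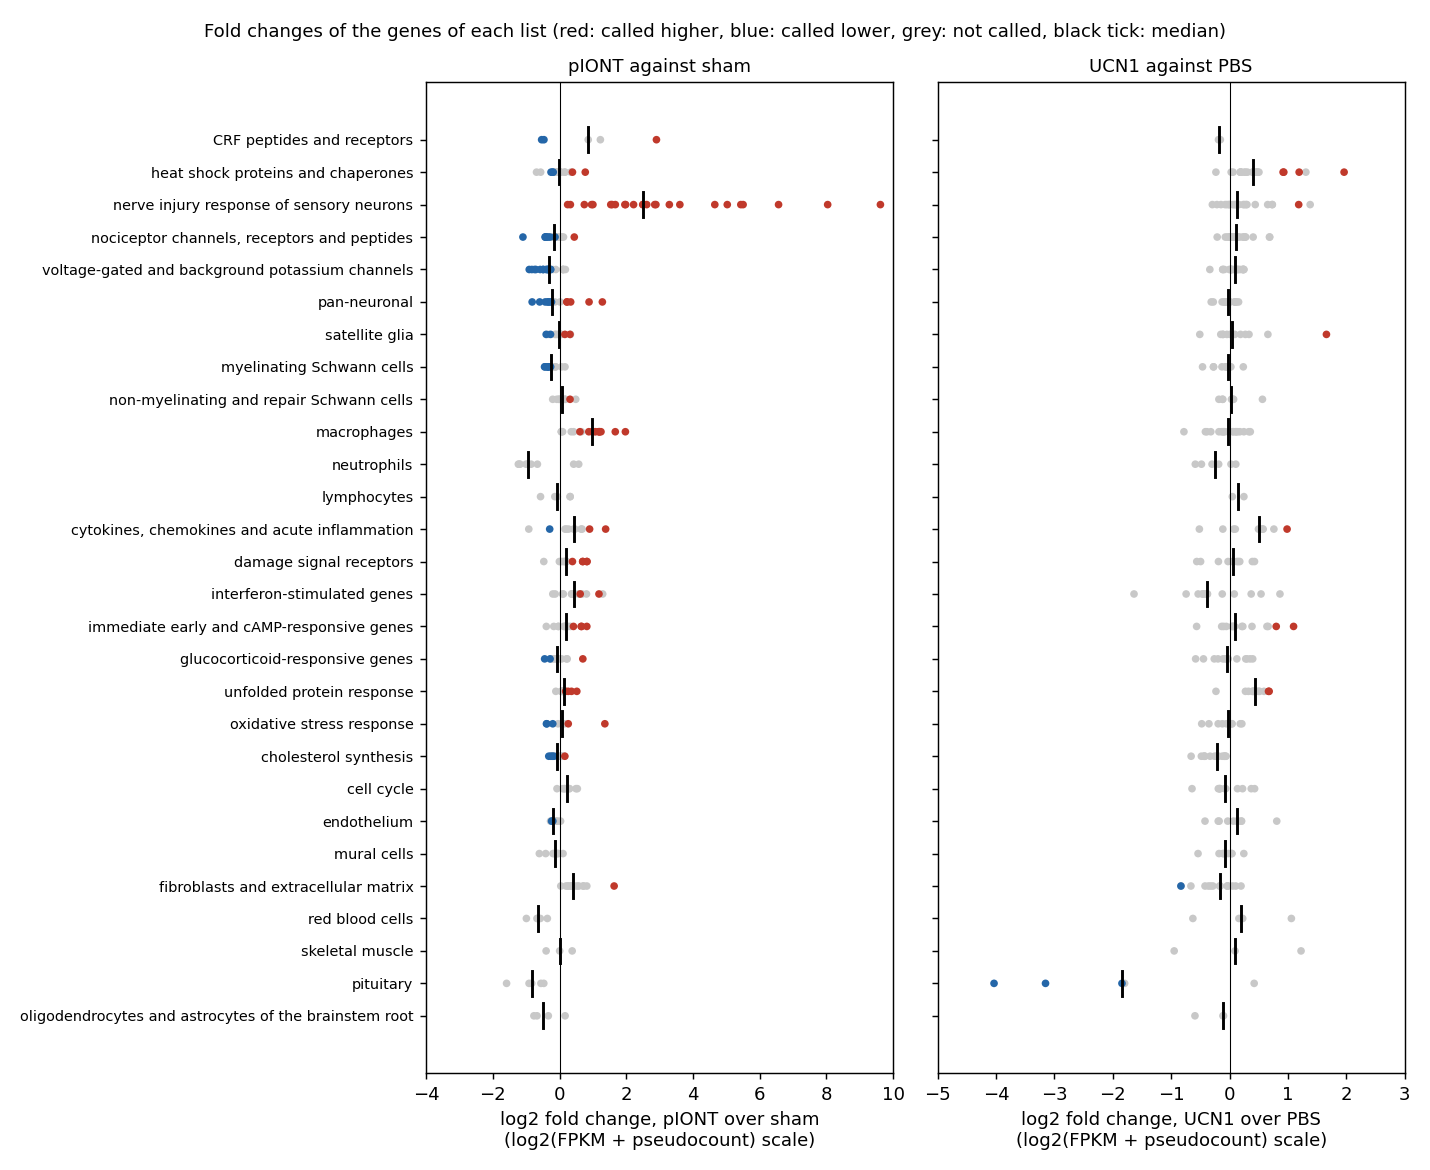
Log2 fold changes of the tested genes of each list (1 line per list, 1 point per gene) for pIONT over sham on the left and UCN1 over PBS on the right, with called genes in red (higher) and blue (lower), other genes in grey and the list median as a black tick. The median of the nerve injury list is 2.51 on the left, and on the right those of heat shock proteins and of the pituitary list are 0.40 and -1.84.

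The last comparison asked which changes the experiments had in common. They share no library. Genes called higher in both were 12, among them Hspb1, Atf3, Socs3, Alkal2, Fosl2, Sbno2, Parp3 and Tmsb10, against 3.93 for independent lists (odds ratio 4.03, 95% interval 1.85 to 8.30, Fisher's exact p = 0.000295, adjusted p = 0.00118 over 4 overlaps). Fisher's test takes genes as independent, which they are not, so its p and interval do not measure the spread between libraries. Fosl2 is a transcription factor of the AP-1 family, and Tmsb10 binds actin monomers. The genes lower in both were Kif19a, a kinesin, and Retnla, against 4.89 for independent lists (Fisher's exact p = 0.224, adjusted p = 0.298). Fxyd5 and Igfbp5 rose in pIONT and fell with UCN1, and Lims2 and Peg10 did the opposite, all 4 named after their values were seen. Among the shared genes, Atf3 had a log2 fold change of 5.03 in pIONT and 1.18 with UCN1, and Hspb1 0.77 and 0.93. The differences between the experiments were not tested.

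**Figure D3:**
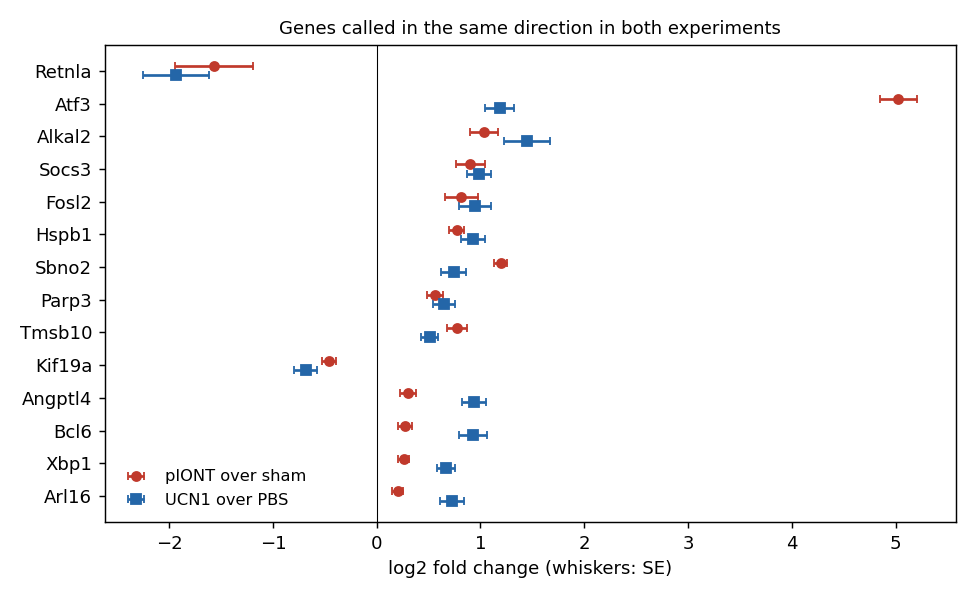
Log2 fold change (horizontal axis, whiskers for the SE) of the 14 genes called in the same direction in both experiments, with circles for pIONT over sham and squares for UCN1 over PBS. Retnla and Kif19a lie below 0 in both experiments and the other 12 genes above 0, with Atf3 at 5.03 and 1.18.

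Across the 13833 genes tested in both experiments the fold changes had a Pearson r of 0.0329 and a Spearman rho of 0.0348, where genes are not independent replicates. Genes below the filter after injection were left out of all these comparisons, among them Sprr1a, Npy and Ecel1. Their means were 0.310, 0 and 0.116 FPKM in PBS and 0.556, 0.261 and 0.158 FPKM in UCN1 libraries. The 1429 genes that rose in pIONT had a mean log2 fold change with UCN1 that was 0.0665 above that of the other genes (limma camera p = 0.0140, and p = 0.319 with an estimated correlation). The 1781 genes that fell in pIONT had a difference of 0.0123, a median of -0.01 and a downward direction in the test, which differ in sign, and did not pass in limma camera. The overlap depended on single libraries, with 3 shared genes without PBS 1 and 0 without PBS 2, UCN1 1 or UCN1 2, and with 7 under TPM, 0 without a filter or a variance trend, 54 with voom and 24 at 10 or more reads. For the raised set, p was 0.0621 without sham 1 and 0.145 without PBS 2.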

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

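Limma-voom on recovered reads and the filter of at least 10 reads were chosen after the results were seen, and the other settings before. For pIONT against sham, 3344 genes became 237 with at least a 2-fold change and 1689 to 2969 when 1 library was left out, the lowest without sham 3, and 2076 without sham 2. For UCN1 against PBS, 97 genes became 59 with at least a 2-fold change, 2 with no filter, 155 at 2 FPKM, 5 without the variance trend, 375 with voom, 177 at 10 reads and 5 to 38 when 1 library was left out. Lists called were 0 in place of 11 and of 9 with an estimated correlation, and 9 to 13 and 7 to 11 when 1 library was left out. Genes called alike in both experiments were 0 with no filter or no trend, 7 under TPM, 54 with voom, 24 at 10 reads and 0 to 13 when 1 library was left out, in place of 14. For the genes raised by pIONT the difference of 0.0665 was no longer past the threshold with an estimated correlation (0.0665, p = 0.319), under quantile normalization (0.0533), without the trend (0.0613) or without sham 1 or PBS 2, and leaving out 1 library gave 0.0479 to 0.0856. For the genes lowered by pIONT the difference of 0.0123 reversed to -0.00554 under quantile normalization, and leaving out 1 library gave -0.0202 to 0.0414, with -0.0202 without PBS 1 and -0.00577 without UCN1 2. Of single values, leaving out 1 library gave -2.85 to 0.48 for Pomc, -1.51 to 0.12 for Prl and -1.03 to 0.60 for Gfap in pIONT, the highest without sham 1, and -1.68 to -0.24 for Gh, which was called without sham 2 (limma adjusted p = 0.0226). With UCN1 it gave -0.48 to 0.11 for Crhr2, the highest without PBS 2, and -0.343 to 0.0280 for Crhr1, the highest without UCN1 1. It gave -0.0193 (without PBS 2) to 0.0869 (without PBS 1) for the correlation of fold changes. None of these values had passed a threshold in the planned fit. Hmgcs1, not called with UCN1, was called with voom and with the block (limma adjusted p = 0.0367 and 0.0311). Where a library is left out of a group of 2, the lone library is assumed to vary like the other group. Array weights called the same 97 genes in the injection experiment and moved no fold change there. The alternatives planned for deposited raw counts were not run, since the tables hold FPKM, and only recovered reads were used for voom. The smaller numbers of samples go with the left-out libraries, and for the other settings the cause was not tested. With the replicate number as a block, 2085 and 260 genes and 13 and 9 lists were called in the 2 experiments. After surgery the deviations of same-numbered libraries correlated at -0.0551, -0.202 and 0.0676. Those of sham 1 and pIONT 2 correlated at 0.231, so the numbers gave no sign of pairing there. After injection the deviations correlated at 0.0387 for equal and -0.0387 for unequal numbers. With 2 libraries per group the deviations mirror each other, so these values cannot decide on pairing.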

Other observations

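The tests of warmth, of carried-over tissue and of the neuronal share, and the gene lists of this part, were chosen only after the results were seen, while the tests of clock genes and of other splits were written before their values were seen.

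In pIONT, 6 of 11 voltage-gated sodium channel genes fell, 8 adjusted over the list alone (median -0.34, limma camera adjusted p = 0.00366, and adjusted p = 0.468 with an estimated correlation). Scn1a fell by 0.65 and Scn8a by 0.43 on the log2 scale, and Scn10a, a channel of nociceptors, by 0.42. Of 10 GABA-A receptor subunits 4 fell and 1 rose (limma camera adjusted p = 0.147), with Gabrb2 at -0.73 and Gabrg1 at 0.69. Of 11 other neuropeptide genes, a list without Npy, Gal and Nts, 4 rose and 1 fell, 4 and 3 adjusted over the list alone (limma camera adjusted p = 0.112). Grp (gastrin-releasing peptide) rose by 2.45, Penk (proenkephalin) by 2.17, Nms by 1.93 and Adcyap1, also in the nerve injury list, by 1.58, and Nmb fell by 0.37. Of 12 complement genes 3 rose, C1qa, C1qb and C1qc at 1.19, 1.20 and 1.17, which are also macrophage genes and kept their calls in 12, 11 and 11 of 18 alternatives (limma camera adjusted p = 0.00366, and adjusted p = 0.468 with an estimated correlation). With UCN1, Cartpt, a peptide gene, rose by 0.86 as the 1 called gene of 9 neuropeptides (limma camera adjusted p = 0.0702), and sodium channels, GABA-A subunits and complement genes had 0 calls (limma camera adjusted p = 0.628, 0.0702 and 0.0702). Clock and meningeal genes in pIONT were not called as lists (limma camera adjusted p = 0.405 and 0.232).

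The first pattern is the higher level of 4 of 22 heat shock and 2 of 13 unfolded protein response genes with UCN1, whose set calls were lost with an estimated correlation (limma camera adjusted p = 0.234 for each). Collection at another time of day would move clock genes, but the median absolute log2 fold change of 12 of them was 0.228. However, Per1 and Per3 were lower adjusted over the list alone and were called with voom (limma adjusted p = 0.0252 and 0.0198). Of the 12 genes 9 had a negative log2 fold change, and Arntl had the largest positive one, at 0.55 (limma adjusted p = 0.390). A median of absolute values leaves direction out, so another time of day is not excluded. Less carried-over tissue would raise pan-neuronal genes by as much, and their median was -0.0262 (SD 0.138) against 0.40. Warmer ganglia at or before collection remain a candidate explanation, since Cirbp and Rbm3, which fall with warmth, fell by 1.00 and 0.75, the weaker change being -0.75. Both were called (limma adjusted p = 0.0137 and 0.0462), and each call was kept in only 10 of 16 alternatives. An effect of UCN1 also stays open.

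The second pattern is the lower level of Gh, Prl and Pomc and of the matrix genes Mfap4 and Fmod with UCN1, where the fibroblast and matrix list had only 1 of 15 genes lower. Unequal carry-over of pituitary tissue is a candidate explanation for the hormone genes. Among sham libraries, which share 1 treatment, the highest and lowest values of Gh, Prl and Pomc differed 7.38-fold, 10.5-fold and 146-fold. The means of PBS and UCN1 differed 17.6-fold, 13.0-fold and 4.97-fold. The sham ratios of Prl and Pomc rest on sham 1. There sham 2 and 3 lay closer together, at 4.55 and 8.37 FPKM for Prl and 1.08 and 2.49 for Pomc. Gh spread over all 3 sham libraries, at 546, 74.0 and 243 FPKM in sham 1 to 3. Within each injection group the Gh values lay close together, unlike among the sham libraries. For carry-over of meninges, 15 of 19 meningeal genes had a negative log2 fold change, with a median of -0.47 (limma camera adjusted p = 1.64e-05, and adjusted p = 0.218 with an estimated correlation). Adjusted over the list alone, 7 were lower and 1 higher. However, the list was written after its 1 called gene, Slc47a1, had been seen among the largest decreases, so its values partly restate the pattern. Carry-over of pituitary tissue or of meninges and a response to UCN1 all divide the same 4 libraries by group, so they cannot be told apart.

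The third pattern is the lower level of 16 of 23 potassium channel, 8 of 22 nociceptor and 7 of 13 myelinating Schwann cell genes in pIONT, whose set calls were lost with an estimated correlation (limma camera adjusted p = 0.737, 0.816 and 0.474). The nociceptor part is weaker, since 4 of the 9 other splits of the libraries gave that list as small a p, against 0 for the other lists of the pattern. Each of those splits mixes both groups, so the 0 is partly built in. A lower share of neuronal RNA alone would raise the genes of every other cell type alike, but 7 myelinating Schwann cell genes were lower and 0 higher while 10 macrophage genes were higher. Those 7 genes are part of the pattern, so this cannot exclude a lower neuronal share together with other changes. Of 15 pan-neuronal genes 7 were lower and 5 higher, with a median of -0.215. A change within neurons and Schwann cells and a change in macrophage number were not tested.

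The surgery groups allow 10 splits of the 6 libraries, too few for a share under 0.05. In either experiment every split but the real one mixes libraries of both groups. The difference between the groups then adds to the spread, so low counts in the other splits are partly built in. The real split called 3344 genes and the highest other split 0, so 1 split gave as many genes. It called 11 lists and the highest other split 15, and 5 of the 10 splits called as many lists. Of the 11 lists, nerve injury, potassium channels, myelinating Schwann cells and damage signal receptors had as small a p in 0 of the 9 other splits, and endothelium in 1. Macrophages, immediate early genes and the unfolded protein response had it in 2, nociceptors in 4, and fibroblasts and interferon-stimulated genes in 6. The injection groups allow 3 splits, also too few, and of the 9 lists called there the cytokine list had as small a p in 1 and the fibroblast list in 2 of the 2 other splits, and the rest in 0.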
